A study of Rattus norvegicus with 3 samples.

How the data were processed

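The series holds 3 single-cell RNA libraries from rat spinal cord, made with a 10x Genomics 3′ kit. Per the labels, each condition used 5 animals aged 6 to 8 weeks, and a section of 5 mm around the injury was digested with collagenase (1 mg/ml, 30 min, 37 °C) and trypsin-EDTA (0.25%, 5 min), strained through a 30-µm mesh and treated to lyse red cells. The labels do not say how the animals of a condition were pooled, and each condition has 1 library. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization, per the file headers. The submitters' processing notes name Cell Ranger 3.0.2 and the mouse builds GRCm38 and mm10, whereas the matrix header gives version 3.1.0 and all 25199 features carry rat Ensembl identifiers. The rat build and annotation release are not given in the sources used here, so no coordinates are reported. Symbols and identifiers were taken from the deposited feature tables.

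The libraries held 1513 (PBS), 2619 (G-HD) and 2339 (MPG-HD) barcodes with 16081082, 26289759 and 23988263 UMIs. Cells with at least 200 detected genes and at most 20% mitochondrial UMIs passed, which were 1377, 2347 and 2091. Scrublet, run within each library through Scanpy 1.11.5 with an expected doublet rate of 6%, called 12 of these 5815 cells (0.206%), far below the expected rate, so the caller was taken as not having worked, although whether doublets were missed was not tested; the called cells were removed all the same. The kept cells were 1374, 2342 and 2087, with 15835089, 25741215 and 23537245 UMIs. Counts were scaled to 10000 UMIs per cell and log-transformed. For clustering, 2000 highly variable genes among those seen in at least 3 cells, picked within 20 expression bins, gave 30 principal components (NumPy). A graph of 20 nearest neighbours (scikit-learn 1.9.0), with edges weighted by the Jaccard index and those under 1/15 dropped, was split by the Leiden method at resolution 0.8 (leidenalg 0.10.2, python-igraph 0.11.9). No batch term was used, since library and treatment are the same.

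Clusters were named from 20 fixed marker sets. The class with the highest mean log2 level of its markers over the other cells (pseudocount 5 CPM) was taken, if at least 3 of its markers were found in at least 20% of the cluster's cells. A cluster stayed unnamed if at least 5 of its 10 leading genes (pseudocount 20 CPM) were cell cycle genes, if its cells held under 1/3 of their library's median UMIs with no marker of the class among those leading genes, or if another class had more markers there. Names are written as "like" classes, since no other marker of identity was measured. Immune or protease genes led some named clusters, Mmp12 in macrophage-like cluster 1, class II genes in macrophage-like cluster 8 and Ifit3 among those of neutrophil-like cluster 16, and cluster 3 was led in part by C1q genes, so these genes also shaped the clusters.

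All statistics are counting statistics, because 1 library per group leaves no replicates and cells are not replicates. No test, p-value, standard error or count of changed genes was computed. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. Levels are UMIs summed over the cells of a class in a library scaled to the total of that sum (CPM), and ratios of libraries carry exact conditional 95% intervals. All intervals cover counting error only and not differences between animals or preparations. Where a sum was 0, the ratio was computed against 3 UMIs as a bound. Genes were compared in the 6 classes with at least 50 cells in each library.

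Before the data were examined, the comparisons, cell filter, clustering settings, marker sets, gene lists, statistics and the rule for named genes were fixed. The rule took genes with at least 50 UMIs in both class sums together, a ratio of at least 2 or at most 0.5, and the same direction when every cell weighs the same, ranked by the interval bound nearest 1. It named the first 10 higher and 10 lower in the class with the most cells and the first 4 higher and 4 lower in the next 2 classes, leaving out mitochondrial, ribosomal protein and haemoglobin genes and features without a symbol. Some of the genes it named are not reported here. From 31 gene lists, members with at least 10 UMIs in both sums together were measured, and a list with at least 3 measured members received a median log2 ratio. Its interval came from 200 Poisson draws of the counts, and its percentile from 10000 random lists of as many genes matched in 20 expression bins. A percentile of 0 or 100 means that the median lay beyond all those lists. Members were counted as higher or lower from 1.5-fold on. List examples are the measured members with the most UMIs. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, leaving out shallower cells.

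Alternatives for the cell filter were none, or at least 500 genes and at most 10% mitochondrial UMIs. Others fixed with the settings above were ignoring the doublet calls, resolutions of 0.4 and 1.2, 1000 variable genes, equal weight for every cell, median-of-ratios scaling, a total without mitochondrial and ribosomal protein genes, a member minimum of 50 UMIs, and thinning to 500 UMIs or none. Added after seeing the data were removing the 6% of cells with the highest doublet scores, equal weight for the clusters of a class, leaving out the cell with the most UMIs of a gene, thinned list medians, shares without neutrophil-like and B-like cells, and shares with each unnamed cluster counted with its nearest class. For thinned list medians the minimum of 10 UMIs was applied again to the thinned sums. They can therefore rest on fewer members, and a shift after thinning is not a measure of depth alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

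The statistics were tested on simulated data with the depths of the macrophage-like sums of G-HD and PBS. Of 95 genes set 2.5-fold apart that held at least 50 UMIs, 91 met the ratio condition, as did all 86 such genes set 4-fold apart. The 95% intervals held the true ratio for 95.4% of 8049 genes, and 19 of 7868 unchanged genes passed (0.241%). Of 200 unchanged lists of 15 genes, 6 had a percentile outside 2.5 to 97.5 (3%), and a list raised 2-fold had a median log2 of 0.99 (0.93 to 1.05). The equal-weight condition was not part of this simulation. Its counts were Poisson draws of the class sums, so coverage near 95% was built in. UMIs clumped in few cells were not simulated, so the share of unchanged genes that passed does not cover such genes.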

Results

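Cells from the injured rat spinal cord were profiled after an injection of PBS, G-HD or MPG-HD at the injury site, in 1 library per treatment. The series title describes a hydrogel depot for severe spinal cord injury, and PBS was taken as the control injection. Total counts were 16081082 UMIs for PBS, 26289759 for G-HD and 23988263 for MPG-HD. After filtering, 1374, 2342 and 2087 cells remained, with medians of 10294, 9247.5 and 10425 UMIs and 2376.5, 2260.5 and 2381 genes per cell. No replicates exist, so every interval below covers counting error only, at 95%.

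The first question was which cells each suspension held. The named immune classes together were 52.3% of PBS cells (49.6 to 54.9), 58.0% of G-HD cells (56.0 to 60.0) and 46.0% of MPG-HD cells (43.9 to 48.2). Macrophage-like cells formed the most abundant class, with 28.2%, 33.0% and 27.3% of cells in PBS, G-HD and MPG-HD. Its largest cluster differed: cluster 3 in PBS (171 of 387 cells) and MPG-HD (271 of 569), and cluster 1 in G-HD (421 of 772). Microglia-like cells made up 16.1%, 9.01% and 12.99%, and both phagocyte classes together 44.3%, 42.0% and 40.2%. Oligodendrocyte-like cells made up 17.7%, 7.77% and 20.2%, fibroblast-like cells 9.97%, 10.1% and 8.05%, and Schwann-like cells 6.84%, 8.58% and 9.92%. The largest fibroblast-like cluster was 13 in PBS and MPG-HD and 11 in G-HD, and the largest oligodendrocyte-like cluster was 5 in PBS and 6 in G-HD and MPG-HD. T-like cells made up 3.71%, 4.48% and 2.54%, oligodendrocyte precursor-like cells 1.82%, 2.22% and 2.87%, endothelial-like cells 2.69%, 1.79% and 1.58%, and monocyte-like cells 1.46%, 0.939% and 0.623%. Unnamed clusters held 7.64%, 10.1% and 10.1%, mostly in cluster 7, nearest to microglia, and cycling cluster 9, nearest to macrophages; counting each with its nearest class put immune cells at 59.9%, 68.1% and 56.2%. No cluster was named astrocyte-like or neuron-like.

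**Figure D1:**
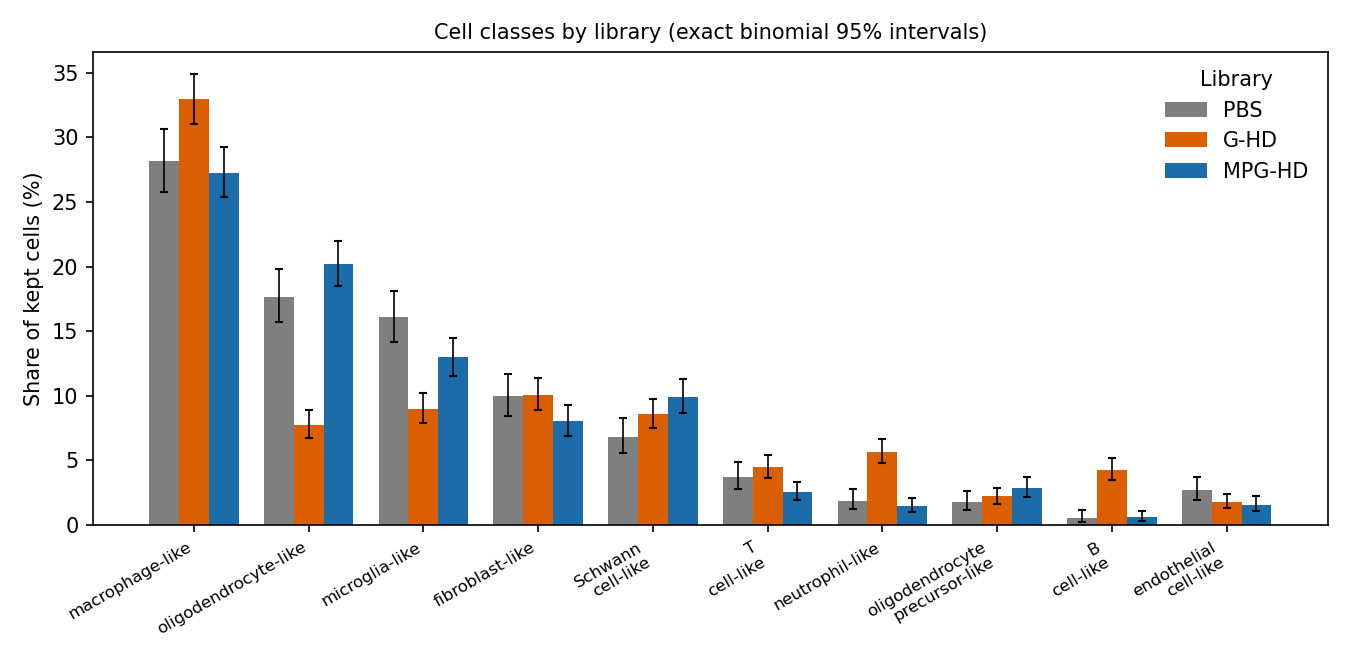
Share of kept cells (%) in each class for the PBS, G-HD and MPG-HD libraries, with exact binomial 95% intervals as error bars. Neutrophil-like cells stand at 5.68% in G-HD against 1.89% in PBS and 1.49% in MPG-HD.

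The comparison of G-HD with PBS asks what the first treatment goes with. The G-HD library held more neutrophils and B cells and fewer oligodendrocytes and microglia. Neutrophil-like cells were 5.68% of G-HD cells and 1.89% of PBS cells, a ratio of 3.001 (1.96 to 4.76), and B-like cells 4.27% and 0.582%, a ratio of 7.33 (3.58 to 17.5). Oligodendrocyte-like cells had a ratio of 0.439 (0.361 to 0.535), microglia-like cells 0.560 (0.462 to 0.680; 0.693 with cluster 7 counted in) and macrophage-like cells 1.17 (1.03 to 1.33). Interferon response genes were higher in G-HD in the class sums of all 3 of the largest named classes. Free RNA from neutrophil-like cells was weighed for the microglia-like cells only.

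In macrophage-like cells, 9 of 17 measured interferon response genes were higher in G-HD than in PBS and 0 were lower, with a median log2 ratio of 0.89 (0.58 to 1.02; percentile 100). Ifitm3, which blocks viral entry, stood at 2.80-fold and Ifi27 at 1.44-fold. Ifit3 (ENSRNOG00000022839), an interferon-induced antiviral gene, was 4.94-fold higher (3.61 to 6.92), although 139 of its 465 G-HD UMIs lay in 1 cell. Rab15 (ENSRNOG00000007364), a small GTPase of endosomal recycling, was 10.5-fold higher (5.19 to 24.6). Growth factor genes had a median of 1.17 (0.35 to 1.25), with 6 of 11 measured higher, 1 lower and Tgfb1 at 2.25-fold. That list also holds Igf2, Mdk and Ptn, leading genes of fibroblast-like cluster 11, and whether RNA of such cells entered was not tested. The elastase Mmp12 was higher at 2.41-fold within a protease list centred on 0.02. Mmp12 leads cluster 1, the largest in G-HD, and stood at 1.74-fold with equal cluster weight. Complement genes had a median of -0.45 (-0.52 to -0.24; percentile 0), with C1qa, C1qb and C1qc at ratios of 0.691, 0.683 and 0.707. Homeostatic microglia genes stood at -0.47 (-0.61 to -0.23), but at 0.070 when the clusters of the class weighed equally, and complement then stood at -0.02, with the C1q genes at 0.997, 1.01 and 1.07. Hspa1b (ENSRNOG00000050647), an inducible heat shock protein, was lower in G-HD, at 0.118 (0.0949 to 0.145). The same direction held in every class with at least 50 UMIs in both sums together. The ratios ran from 0.0418 in microglia-like to 0.810 (0.755 to 0.870) in fibroblast-like cells.

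Other named macrophage genes rested on few cells or are typical of other cell types. Of those higher in G-HD, Trh had 136 of 166 UMIs in 1 cell, Ly6d 158 of 159, Myoc 61 of 71, Dcn 226 of 347, Apod 1312 of 1876 and Rbp2 35 of 65, the latter at least 9.90-fold higher against 0 UMIs in PBS. Dcn (6.34) and Igfbp7 (8.23) had their highest levels in fibroblast-like and mural-like cells. Of those lower, a single PBS cell per gene held all 414 UMIs of Nppb, 298 of 315 of the B cell attractant Cxcl13, 120 of 127 of Ccl17, 48 of 52 of Cxcl9, 154 of 232 of Mfge8, 62 of 92 of Cst6 and 50 of 94 of Mustn1. Mt3, highest in ependymal-like cells, was at 0.0494 (0.0371 to 0.0647), with 190 of 546 PBS UMIs in 1 cell. Cxcl13 was higher in G-HD at resolution 0.4, with a log2 ratio of 2.22. Trpc6, a calcium channel gene, was lower at 0.186. Collagens stood at 1.72 (6 of 7 measured higher, 1 lower), other matrix genes at 0.62 and chondroitin sulfate proteoglycans at 0.32. Neutrophil granule genes stood at 0.50 and myelin genes at -0.27, which are genes of cell types whose shares differed between these libraries.

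The remaining lists in macrophage-like cells had medians between -0.36 and 0.38. Hypoxia and glycolysis genes were at 0.28 (0.23 to 0.33), with Aldoa at 1.22-fold, Eno1 at 1.19-fold and Ldha at 1.29-fold. Antigen presentation stood at -0.28 (-0.36 to 0.00), with Cd74 at 0.774, and at 0.11 after thinning, which can leave fewer members measured. Pro-inflammatory mediators had a median of -0.05, in which Il1b was at 1.39-fold and Tnf at 0.425. Chemokines were at 0.03, alternative activation at 0.07, lipid-associated phagocyte genes at 0.01, lysosomal genes at 0.07, cholesterol handling at 0.02, and NF-kB targets at -0.23. Reactive astrocyte genes stood at -0.05, angiogenesis at -0.36, axon guidance at 0.08, antioxidant genes at 0.01, iron handling at 0.16 and oxidative phosphorylation at -0.03. S phase genes were at -0.21, G2/M genes at 0.38, immediate early genes at -0.01, heat shock genes at -0.04 and apoptosis genes at 0.14. Cell cycle medians of macrophage-like cells, here and below, leave out cycling cluster 9, which the naming rule left unnamed.

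In microglia-like cells the interferon difference was larger. Of 17 measured genes, 14 were higher in G-HD and 0 lower, with a median of 1.85 (1.56 to 2.01; percentile 100). Mx1 was 3.60-fold higher, Isg15 5.67-fold and Mx2 4.56-fold, all antiviral effectors. Ifit3 was 16.4-fold higher (11.5 to 24.1), Ifit2 (ENSRNOG00000036604) 8.65-fold (6.10 to 12.6) and Usp18 (ENSRNOG00000037198), which removes ISG15 from proteins and dampens interferon signalling, 8.36-fold (5.62 to 12.9). RT1-Bb (ENSRNOG00000032708), a class II chain, was 9.78-fold higher (6.00 to 16.9). Antigen presentation genes had a median of 0.39 (0.33 to 0.74), with 6 of 14 higher and 0 lower, Cd74 at 4.42-fold and RT1-Da at 4.66-fold. Their median was 0.79 after thinning, over the members still measured then. Unthinned, Cd74 was found in 47.4% of microglia-like cells in G-HD and 36.2% in PBS, and RT1-Bb in 15.6% and 4.52%. For each gene, most G-HD cells of the class held no UMI, and the Cd74 share differed less than its level. Macrophage-like cells mixed into this cluster are weighed below for the class II genes. Hspa1b was at 0.0418 (0.0220 to 0.0724), the P450 gene Cyp2d3 (ENSRNOG00000029179) at 0.0455 (0.0145 to 0.109), Fam111a (ENSRNOG00000012067), a protease gene, at 0.254 (0.189 to 0.337), and Rhox5 at 0.209. Chemokines stood at 0.16, alternative activation at 0.30 with Tgfb1 at 2.20-fold, homeostatic genes at -0.14, and immediate early genes at -0.23. Neutrophil granule genes stood at 1.96, with all 5 measured members higher.

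**Figure D2:**
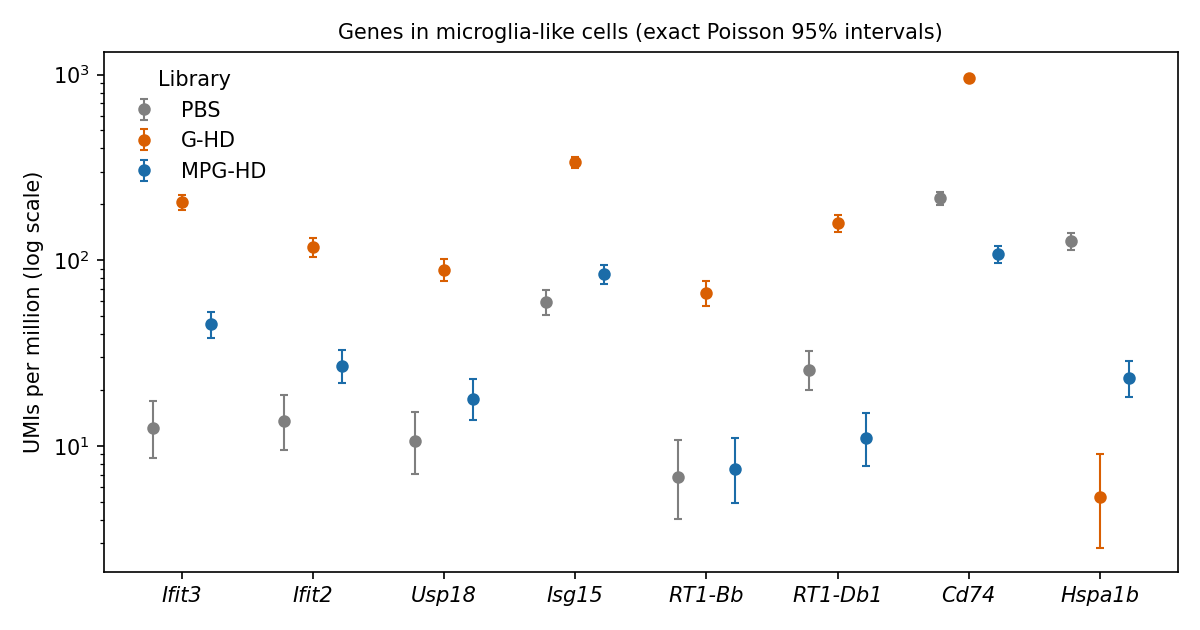
Level of Ifit3, Ifit2, Usp18, Isg15, RT1-Bb, RT1-Db1, Cd74 and Hspa1b in the microglia-like cells of each library (CPM, log axis), with exact Poisson 95% intervals. In G-HD, Ifit3 stands 16.4-fold above PBS and Hspa1b at 0.0418 of PBS.

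In oligodendrocyte-like cells all 13 measured interferon genes were higher in G-HD (median 1.54, 1.14 to 1.87), with Ifi27 at 1.99-fold, Mx2 at 2.14-fold and Isg15 (ENSRNOG00000021802) at 31.8-fold (12.02 to 119; 33 of 94 G-HD UMIs in 1 cell). Isg15 was found in 7.14% of these G-HD cells and was highest in neutrophil-like cells, whose free RNA was not tested as a source here. Antigen presentation genes stood at 1.85, with 9 of 12 higher, 1 lower and RT1-A1 at 2.78-fold. Lists typical of leukocytes were higher too: granule genes at 3.41 (4 of 4 measured), lipid-associated phagocyte genes at 0.31 (6 of 15), lysosomal genes at 0.26 (percentile 100), and chemokines at 0.82 (4 of 7, 1 lower), or -0.077 with the stricter cell filter. Myelin genes had a median of 0.00 (-0.02 to 0.03), with Mbp at 1.00. Car2, a carbonic anhydrase of oligodendrocytes, was lower at 0.365 (0.297 to 0.445), and Sbsn at 0.355. Trh was at 0.242, with 107 of 168 PBS UMIs in 1 cell. Immediate early genes had a median of 0.38, with Fos at 1.30-fold and Jun at 1.37-fold. The neutrophil genes S100a8 (71.0-fold, 317 of 367 UMIs in 1 cell) and S100a9 (17.8-fold, 121 of 158) held most of their G-HD UMIs in 1 cell. S100a8 and S100a9 were found in other cells too, in all in 40 and 32 of 182 G-HD cells. In PBS they were found in 7 and 12 of 243 cells. The small heat shock gene Hspb1 (11.8-fold, 151 of 165 UMIs in 1 cell) and Stard6 (0.213, 61 of 70 PBS UMIs in 1 cell) rested on single cells. Without that cell Stard6 had a log2 ratio of 0.60, and Hspb1 stood at -0.41 once the cells with the highest doublet scores were removed. Neuron and synapse genes stood at 0.20 in these cells.

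The comparison of MPG-HD with PBS asks the same of the second treatment. Composition lay closer to PBS than in G-HD for neutrophil-like cells (ratio 0.785, 0.451 to 1.38), B-like cells (1.07, 0.411 to 2.98) and oligodendrocyte-like cells (1.14, 0.972 to 1.34). Schwann-like cells had a ratio of 1.45 (1.13 to 1.87), microglia-like cells 0.807 (0.673 to 0.969) and endothelial-like cells 0.587 (0.356 to 0.965). The microglia-like ratio was 0.985 with 1000 variable genes and 0.948 with cluster 7 counted in. Interferon genes were again higher than in PBS in macrophage-like and oligodendrocyte-like cells.

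In macrophage-like cells, 7 of 16 measured interferon genes were higher in MPG-HD and 0 lower (median 0.52, 0.47 to 0.77; percentile 100). The median was 0.31 with equal cluster weight and 0.44 with the stricter cell filter. Ifitm3 (ENSRNOG00000015078) was 4.13-fold higher (3.29 to 5.23; 2.36-fold with equal cluster weight), Isg15 2.78-fold and Ifi27l2b 3.51-fold. Cyp2d3 was 4.05-fold higher (3.15 to 5.26) and Rab15 8.38-fold (4.09 to 19.96). Abcb10, a mitochondrial transporter gene, stood at 3.50-fold. The metalloproteases Mmp7 and Mmp9 were lower, at 0.119 (0.0890 to 0.155) and 0.120 (0.0682 to 0.198). Mmp9 was highest in neutrophil-like cells, and 43 of its 103 PBS UMIs lay in 1 cell. Serping1 (ENSRNOG00000007457), the C1 inhibitor, was at 0.186 (0.170 to 0.203), Mt3 at 0.0589 (0.0428 to 0.0794) and Nol10 at 0.224. Genes with most of their UMIs in 1 cell were Ocm2 (48 of 50 UMIs) and Ccl22 (70 of 116) among those higher. Among those lower they were Nppb, Cst6, Mustn1 and Cxcl9, in the PBS cells given above. Without the cell with the most UMIs in each library, Cxcl9 had a log2 ratio of 0.25.

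Lists for MPG-HD over PBS in these cells centred on -0.14 for lipid-associated phagocyte genes (-0.19 to -0.10), with Spp1 at 0.604, on -0.21 for hypoxia and glycolysis, with Ldha at 0.771, and on -0.20 for proteases, with Mmp12 at 0.839. Complement stood at -0.01, antigen presentation at -0.14, pro-inflammatory mediators at -0.07, chemokines at -0.08, alternative activation at -0.10 with Tgfb1 at 1.82-fold, and growth factors at 0.18. Granule genes stood at -1.13 and reactive astrocyte genes at -0.34.

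In microglia-like cells the interferon median for MPG-HD over PBS was 0.20 (0.06 to 0.41), with 5 of 17 higher and 1 lower, and -0.25 after thinning. Ifit3 was 3.62-fold higher (2.47 to 5.44), the decoy interleukin-1 receptor gene Il1r2 4.34-fold and Enpp6, a gene of newly forming oligodendrocytes, 4.63-fold. Fam111a stood at 0.0445 (0.0245 to 0.0747), Hspa1b at 0.183 (0.142 to 0.234), Ccl12 at 0.255, with 25 of 60 PBS UMIs in 1 cell, and Cxcl13 at 0.361. Antigen presentation genes had a median of -0.41, with 6 of 14 lower and 0 higher, and chemokines one of -0.36. After thinning the antigen presentation median was -0.095. Both thinned medians cover only members that still met the UMI minimum, so these shifts cannot be read as an effect of depth alone. In oligodendrocyte-like cells, 8 of 11 interferon genes were higher (median 0.77, 0.56 to 0.95). The list median was 0.41 after thinning and 1.17 with equal cell weight. Oasl2 was at 5.18-fold, but at a log2 ratio of -0.45 after thinning. The growth arrest gene Gadd45g was 2.71-fold higher (2.51 to 2.93) and the mitochondrial ribosomal gene Mrpl43 5.03-fold, and immediate early genes had a median of 0.53. The cholesterol synthesis gene Hmgcs1 was lower at 0.363 (0.309 to 0.425), Rnd3 at 0.172, Trh at 0.325 and Stard6 at 0.122, the last 2 mainly through the PBS cells given above (log2 ratios of -0.72 and -0.29 without the cell with the most UMIs), and myelin genes had a median of -0.04.

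**Figure D3:**
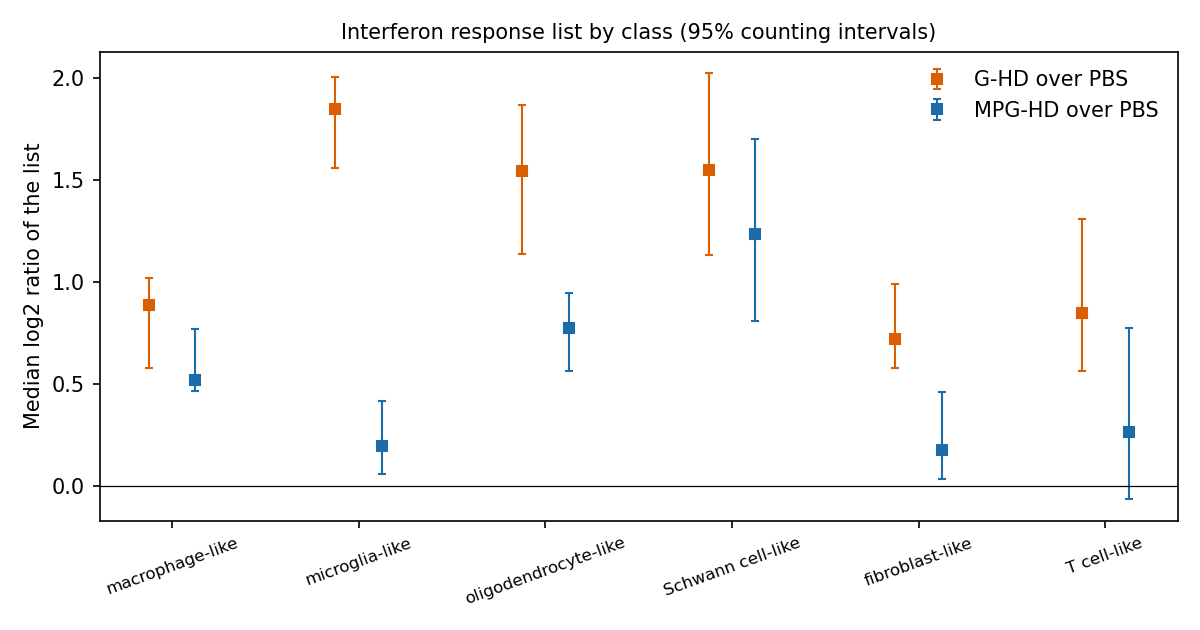
Median log2 ratio of the interferon response list in 6 classes, G-HD over PBS and MPG-HD over PBS, with 95% counting intervals. In microglia-like cells the medians are 1.85 for G-HD and 0.20 for MPG-HD.

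The comparison of MPG-HD with G-HD asks how the treatments differ from each other. MPG-HD held fewer neutrophil-like cells (ratio 0.262, 0.171 to 0.389), B-like cells (0.146, 0.0751 to 0.261) and T-like cells (0.566, 0.399 to 0.795) than G-HD. It held more oligodendrocyte-like cells (2.60, 2.18 to 3.11) and microglia-like cells (1.44, 1.199 to 1.73). Interferon and class II genes were lower in its microglia-like cells. Interferon genes had a median of -1.65 there (-1.83 to -1.56), with 15 of 17 lower and 0 higher, and antigen presentation genes one of -0.96, with 9 of 14 lower.

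Among class II genes of microglia-like cells, RT1-Db1 (0.0696), RT1-Ba (0.0838) and RT1-Da (0.102) were lower in MPG-HD, as was the invariant chain Cd74 (ENSRNOG00000018735), at 0.113 (0.101 to 0.126). Cyp2d3 was 53.9-fold higher (22.9 to 167), Hspa1b 4.38-fold (2.42 to 8.59), Enpp6 3.88-fold and Cox6b2 3.11-fold. In oligodendrocyte-like cells, interferon genes had a median of -0.60 (-0.40 with the stricter filter and -1.20 with equal cluster weight). Granule genes had one of -3.56 (5 of 5 lower), chemokines -1.14 (8 of 9, 1 higher), complement -1.003 (6 of 7) and lipid-associated phagocyte genes -0.92 (8 of 15). Mrpl43 was 7.44-fold higher, Sbsn 2.78-fold, Alyref 2.57-fold and Ltbp4 2.88-fold. S100a9, S100a8 and Hspb1 were lower there, with most of their G-HD UMIs in the single cells given above, although S100a8 and S100a9 were found in other G-HD cells too. Pf4 was at 0.107 with 25 of 59 UMIs in 1 cell, and at a log2 ratio of 0.10 without the highest doublet scores.

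In macrophage-like cells of MPG-HD against G-HD, Cyp2d3 was 3.81-fold higher (3.18 to 4.57), Hspa1b 3.84-fold (3.07 to 4.82), Fam169b 4.91-fold, Gal3st4 3.88-fold, Clec2l 3.51-fold and Nradd 2.84-fold. With equal cluster weight the last 4 stood at 2.38, 2.05, 2.30 and 1.79, and the first 3 of these 4, like Cyp2d3, were highest in microglia-like cells. Mfge8, which bridges apoptotic cells to phagocytes, was at 2.92-fold with 61 of 238 UMIs in 1 cell. Ccl22, Ccl17 (109 of 160) and Ocm2 were higher, each with most of its MPG-HD UMIs in 1 cell. Serping1 was lower at 0.270 (0.248 to 0.294), the neutrophil genes S100a9 at 0.0749, S100a8 at 0.175 and Ngp at 0.0180, and the fibroblast genes Islr at 0.0864 and Dcn at 0.181, the latter at a log2 ratio of -1.05 without the cell with the most UMIs. Ly6d, Trh, Rbp2 and Myoc were lower, with most of their G-HD UMIs in the single cells given above. The interferon median was 0.15 (0.00 to 0.25), and -0.16 under the stricter cell filter. Homeostatic genes stood at 0.45, complement at 0.21 (-0.0017 with equal cluster weight), myelin genes at 0.68 (0.49 to 0.84; 7 of 12 higher, 1 lower), G2/M genes at -0.71 (7 of 14 lower), proteases at -0.23 with Mmp12 at 0.348 (0.511 with equal cluster weight), hypoxia and glycolysis at -0.36, collagens at -1.77, granule genes at -2.02, and neuron and synapse genes at 0.80 (-0.64 to 1.70; 3 measured).

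Shares of cells with a UMI, after thinning to 1000 UMIs, put single genes on an equal depth in PBS, G-HD and MPG-HD. Among microglia-like cells, Ifit3 was found in 1.82% (0.498 to 4.59), 14.8% (10.3 to 20.3) and 2.96% (1.29 to 5.75), and Isg15 in 6.82%, 20.5% and 5.19%. Cd74 was found in 14.1% (9.78 to 19.4), 21.4% (16.1 to 27.6) and 5.56%, and its PBS and G-HD intervals overlapped. The cytokine gene Il1b was found in 58.2%, 69.5% and 54.8%. Unthinned, these shares were 7.69%, 33.6% and 14.4% for Ifit3, 26.2%, 51.2% and 26.9% for Isg15, 36.2%, 47.4% and 25.5% for Cd74, and 81.4%, 88.2% and 83.0% for Il1b. Oligodendrocyte-like cells served for comparison; their own interferon and class II genes differed between libraries, so their shares are at most an upper limit for background. The thinned shares there were 0.474%, 0.621% and 0% (upper limit 0.954) for Ifit3, 0% (upper limit 1.73), 1.86% and 0.519% for Isg15, 0% (1.73), 3.11% and 0% (0.954) for Cd74, and 0% (1.73), 1.24% and 0.519% for Il1b. Median depths were 11329, 11514 and 12432 UMIs in microglia-like and 10807, 11476 and 12040 in oligodendrocyte-like cells. Thinning left out 1 microglia-like cell per library and 32, 21 and 36 oligodendrocyte-like cells. The heat shock gene Hspa1b was found in 13.6%, 0.952% and 3.70% of microglia-like cells (47.1%, 4.27% and 20.7% unthinned) and in 16.1%, 5.59% and 10.4% of oligodendrocyte-like cells, which hold this gene themselves and so give no background for it.

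Among macrophage-like cells, with median depths of 14457, 16015.5 and 14465 UMIs and 2, 8 and 1 cells left out, the mannose receptor gene Mrc1 was found in 12.5%, 10.2% and 13.4% (61.0%, 67.7% and 64.9% unthinned), against 0% (1.73), 0.621% and 0% (0.954) in oligodendrocyte-like cells. Il1b was found in 25.5% (21.2 to 30.1), 33.8% (30.4 to 37.2) and 28.9% (25.2 to 32.8), and in 55.3%, 63.9% and 63.6% unthinned. Arginase gene Arg1 was found in 0.260%, 1.18% and 0.880% (6.98%, 9.84% and 7.03% unthinned), Tnf in 1.82%, 0.524% and 1.76% (20.2%, 12.05% and 13.01%), and the proliferation gene Mki67 in 0.519%, 0.262% and 0.880% (4.39%, 7.12% and 5.10%). The Mki67 shares describe the class without cycling cluster 9, nearest to macrophages, which the naming rule left unnamed. Oligodendrocyte-like shares of Arg1 and Mki67 were 0% with upper limits of 1.73%, 2.27% and 0.954%, so differences between libraries were not detectable at this depth. For Tnf they were 0.474%, 0% (2.27) and 0% (0.954). Nos2, the inducible nitric oxide synthase, was found in 0% of thinned cells in each library, with upper limits of 0.954%, 0.482% and 0.647%, and in 0.258%, 0% and 0% unthinned. These limits are for cells with a UMI and not for cells that express the gene.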

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

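The tests of granulocyte precursor genes and of the clustering settings were chosen only after the results were seen, and the test of B precursor genes was set before.

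The share of barcodes with over 20% mitochondrial UMIs was 10.1% in G-HD and 9.96% in MPG-HD, above the 7.87% of PBS; these barcodes were left out of the comparisons. Haemoglobin genes, which the comparisons did not use, reached 1573 CPM in G-HD and 677 in MPG-HD against 516 in PBS. Cluster 7, which stayed unnamed, held 6.47% of MPG-HD cells (5.45 to 7.61) and 4.44% of PBS cells (3.41 to 5.67).

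Genes of blood cell precursors, taken over all kept cells rather than within a compared class, stood above PBS in G-HD. The primary granule genes Elane, Mpo and Prtn3 reached 23.3 CPM in G-HD (600 UMIs) against 0.253 in PBS (4 UMIs) and 0.340 in MPG-HD (8 UMIs), and 547 of the G-HD UMIs lay in 6 of the 101 G-HD cells of cluster 9. The B cell precursor genes Rag1, Rag2, Vpreb1, Igll1 and Dntt together reached 25.3 CPM in G-HD against 11.999 in PBS and 10.9 in MPG-HD, although 208 of the 375 Dntt UMIs of G-HD lay in macrophage-like cluster 1.

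The larger shares of neutrophil-like and B-like cells in G-HD were weighed against the cell filter, doublet handling and clustering. Those choices are argued against, since the lowest ratio to PBS under 8 settings was 2.92 and the highest 11.7. Marrow cells in the suspension remain a candidate source: 30% of the B-like cells of G-HD (21.2 to 40.0) carried a UMI of a B precursor gene against 0% of its T-like cells (upper limit 3.45%), and 12.03% of its neutrophil-like cells (7.04 to 18.8) carried Elane, Mpo or Prtn3, again against 0% of T-like cells (upper limit 3.45%). Marrow could bring both cell types without a difference in the cord itself, but precursor cells entering from blood would look alike here. A response to the treatment also stays open, as it was not tested, and 1 library per treatment leaves differences in dissection and preparation open.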

How the results depend on the processing

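The added alternatives (removing high doublet scores, equal cluster weight, leaving out the top cell, thinned list medians, shares without neutrophil-like and B-like cells, unnamed clusters counted with their nearest class) were chosen only after the results were seen. No paired analysis was possible because each treatment has 1 library and no animal links the libraries, and no library can be left out for the same reason. Of 237 share ratios recomputed, 230 stayed within their intervals and 0 reversed; of 237 shares, 179 stayed and 58 moved, and of 66 shares of cells with a UMI, taken at other depths, 14 stayed and 52 moved; of 1145 values of named genes, 951 stayed, 186 moved and 8 reversed; of 1515 list medians, 1267 stayed, 234 moved and 14 reversed, where a reversal was counted for medians with a percentile outside 2.5 to 97.5. For 21 results of named genes, 43 recomputed values are missing. Either both sums held at most 3 UMIs or, with equal cell or cluster weight, a library had a level of 0. The macrophage-like share ratio of MPG-HD over G-HD was 0.718 without a filter, 0.685 with the stricter filter, 0.658 at resolution 0.4 and 0.704 with 1000 variable genes; over PBS it was 0.845 at resolution 0.4, and the microglia-like ratio 0.985 with 1000 variable genes; the latter was 0.693 for G-HD over PBS with unnamed clusters counted in. Log2 ratios that changed sign were, in macrophage-like cells, Cxcl13 (G-HD over PBS) at 2.22 and Cxcl9 (MPG-HD over PBS) at 0.63, both at resolution 0.4, and Cxcl9 at 0.25 without the top cell. In oligodendrocyte-like cells they were Hspb1 (G-HD over PBS) at -0.41 and Pf4 (MPG-HD over G-HD) at 0.10 without high doublet scores, Stard6 (G-HD over PBS) at 0.39 thinned and 0.60 without the top cell, and Oasl2 (MPG-HD over PBS) at -0.45 thinned. The interferon response median in macrophage-like cells was 0.58 with equal cell weight (G-HD over PBS), 0.44 with the stricter filter and 0.31 with equal cluster weight (MPG-HD over PBS), and -0.16 and -0.18 under the same alternatives (MPG-HD over G-HD). In oligodendrocyte-like cells it was 2.10 (G-HD over PBS) and 1.17 (MPG-HD over PBS) with equal cell weight, 0.41 thinned (MPG-HD over PBS), and -0.40 with the stricter filter and -1.20 with equal cluster weight (MPG-HD over G-HD). In microglia-like cells it was -0.25 thinned (MPG-HD over PBS), and -1.29 with the stricter filter and -1.97 thinned (MPG-HD over G-HD). Thinned antigen presentation medians were 0.11 in macrophage-like cells and 0.79 in microglia-like cells (G-HD over PBS) and -0.10 in microglia-like cells (MPG-HD over PBS). With equal cluster weight, homeostatic microglia genes stood at 0.070 (G-HD over PBS) and complement at -0.0017 (MPG-HD over G-HD) in macrophage-like cells, and antioxidant genes at 0.095 in oligodendrocyte-like cells (MPG-HD over PBS). Other oligodendrocyte-like medians that changed sign were chemokines at -0.077 with the stricter filter (G-HD over PBS) and, for MPG-HD over PBS, lipid-associated genes at 0.18 with equal cell weight and 0.14 thinned, cholesterol handling at 0.091 thinned and complement at 0.39 with equal cell weight. Thinned microglia-like medians for MPG-HD over PBS were 0.042 for pro-inflammatory mediators, 0.24 for reactive astrocyte genes and -0.081 for S phase genes. In each of these cases the cause was not tested, and thinned list medians can rest on fewer members than the unthinned ones.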

Other observations

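Of the tests below, those of neutrophil RNA and of admixed macrophages were set before their results; the tests of free RNA and of genotype were chosen only after the results were seen.

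Other cell classes carried interferon and chemokine differences too. In Schwann-like cells, interferon response genes had a median log2 ratio to PBS of 1.55 in G-HD (13 of 15 measured higher) and 1.24 in MPG-HD (11 of 13), and chemokines 2.55 and 0.71. In fibroblast-like cells, chemokines stood at 1.77 in G-HD (11 of 14 higher, 1 lower) and 1.00 in MPG-HD, and interferon genes at 0.72 and 0.17. T-like cells had interferon medians of 0.85 and 0.26. Free RNA of leukocytes was not tested as a source of the interferon and chemokine genes in these classes. The lists of Schwann-like, fibroblast-like and T-like cells were also not recomputed under the alternative settings. G2/M genes of fibroblast-like cells were lower in MPG-HD than in PBS for all 15 measured members, with a median of -3.54 (-4.30 to -2.88), and stood at -0.11 in G-HD. PBS held 137 fibroblast-like cells, and how many of them carried these UMIs was not counted. The members may share a few cycling cells, which the interval does not cover. Over all kept cells, the G2/M gene Top2a was at 20.9 CPM in PBS, 28.2 in G-HD and 16.1 in MPG-HD, and cycling cells also formed the unnamed cluster 9.

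In the microglia-like cells of G-HD, interferon response and class II genes were both higher than in PBS, and each was weighed on its own. Free RNA from neutrophil-like cells is argued against for the interferon genes, since the S100a8 and S100a9 counts in these cells bring 0.0141% of the excess (upper limit 0.0174). The median stayed within its interval under all alternatives run, but none of them removes free RNA, so this does not bear on that source. Equal cluster weight could not change the median, since cluster 2 alone forms this class. For the class II genes, free RNA in the suspension is argued against, because the excess in Schwann-like or oligodendrocyte-like cells was at most 4.33% of that in microglia-like cells (upper limit 5.26). Macrophage-like cells of cluster 8 mixed into the cluster may account for part of the class II excess: the excess would need a share of 6.03%, and 54.8% of the Mrc1, Lyve1, Clec10a and F13a1 excess which that share would bring was found (38.1 to 71.4; 154 UMIs in G-HD, 65 in PBS). A response of microglia to the treatment and a difference in library preparation stay open and untested.

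Cyp2d3 and Fam111a differed several-fold between libraries in microglia-like cells, which could come from strain variants between the animals, although the labels call all of them wild type; this was first examined over the genes together and then gene by gene. For Fam111a a genotype acting alike in every cell type is argued against, since MPG-HD over PBS was 3.19 in fibroblast-like cells (2.17 to 4.79) and 0.0445 in microglia-like cells; the other 3 classes with enough UMIs lay below 1, at 0.0631 in endothelial-like, 0.640 in macrophage-like and 0.854 in Schwann-like cells (0.526 to 1.41). For Cyp2d3 the same is argued against only by G-HD over PBS, the comparison taken because its classes lay farthest apart. There the ratio was 1.06 in macrophage-like cells (0.804 to 1.42) and 0.0455 in microglia-like cells (0.0145 to 0.109). In the other comparisons both classes were higher in MPG-HD, at 4.05 and 2.45 over PBS and at 3.81 and 53.9 over G-HD. Their direction there does not speak against such a genotype. Only these 2 classes held enough UMIs. A genotype that acts in some cell types only was not tested and stays open.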
